A study of Homo sapiens with 24 samples.

How the data were processed

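Poly(A) RNA of SET2 cells was fragmented with RNase III and sequenced on the Ion Proton after 16 PCR cycles, per the labels. Cells were grown in RPMI1640 with 20% FCS, and the persistent lines were kept in their inhibitor. The 24 libraries form 8 groups of 3, and 9 libraries were run again or on 2 lanes but appear as 1 column each. The deposited table holds 25082 genes as a normalised signal, made by the authors from counts divided by 1 size factor per library. The authors' notes name BWA 0.7.5.1, HTSeq 0.5.3p3 and DESeq 1.10.1 and the builds hg19 and GRCh37 without saying what each was used for. Every value was a whole multiple of 1 step per library within 0.01, and dividing by the step gave whole reads, 21770721 to 36160750 per library. In 3 libraries the step is within 0.01 of 1, so for them this says nothing of how the values were made. The table gives symbols only, of which 18697 matched a current or older symbol, and no coordinates are printed because the annotation at hand is of another build.

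Values were log2-transformed after adding 1, and the 20154 genes with a normalised count of at least 10 in at least 3 samples were tested. A single limma 3.58.1 fit (R 4.3.3, empirical Bayes with trend, 16 residual degrees of freedom) covered the 8 groups, with two-sided tests, Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The comparisons were each persistent line and their mean against naive cells, each pair of lines, INC424 at 4 h and 48 h against DMSO, 48 h against 4 h, the INC424 persistent line against 48 h, and DMSO against naive. Groups, comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined.

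The 32 lists, with 634 entries of which 626 are in the table, 2 of them by another symbol, cover signalling (JAK-STAT targets, MAPK output, immediate early genes, interferon response, receptors, negative regulators, NF-kB), antigen presentation (MHC class I and II), growth (MYC targets of ribosome biogenesis, ribosomal proteins, S phase, G2 and M phase), lineage (megakaryocyte, erythroid, granulocyte and monocyte, stem and progenitor), stress and metabolism (ATF4, endoplasmic reticulum chaperones, heat shock, cholesterol, glycolysis and hypoxia, oxidative phosphorylation, p53, FOXO, NRF2), survival and drug efflux (BCL2 family, ABC transporters), and other cell types or RNA quality (lymphoid, fibroblast and epithelial, mitochondrially encoded, replication-dependent histones for poly(A) selection). Each was tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. A list needed 3 members tested.

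Named genes follow a rule. For the mean of the lines, INC424 at 4 h and 48 h, and the INC424 line against 48 h, they are the 6 largest rises and 6 largest falls past the threshold with a symbol, a mean of at least 50 over the samples compared and no overlap between the groups. For each line and each pair of lines the numbers are 3 and 3. From each list up to 4 members with the largest change past the threshold may be named, or up to 2 with the highest mean where none passes, along with JAK1, JAK2, JAK3, TYK2, STAT5A and STAT5B. Of the genes the rule allows, some are not reported here. Marker genes of other cell types, and genes followed from one comparison into another or picked for plots, were chosen after their values were seen. Where a group had 0 reads the fold is a bound against 3 reads over the group, and where it had 1 to 3 reads a 95% Clopper-Pearson interval of the ratio is given; both cover counting error only.

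Alternatives were pseudocounts of 0.5 and 10, no filter and a filter at 50, TMM (edgeR 4.0.16) and upper-quartile scaling, empirical Bayes without trend or robust, sample quality weights, fits of the compared groups alone, a replicate block, a run-again term, edgeR and DESeq2 1.42.0 on the recovered reads, and leaving out each library in turn. Those added after seeing the data leave out CYT387 persistent library 2, the 4 libraries richest in epithelial RNA, or the 1018 genes tested that were over 8 times higher in that library than in the mean of libraries 1 and 3 on counts plus 10. On simulated data with 200 changed genes the INC424 4 h test recovered 22.4%, 56.7% and 87.9% of genes changed 1.5, 2 and 4 times. It called 4 of 19929 unchanged genes. For the mean of the lines these were 32.8%, 76.1%, 93.9% and 10. A shifted S phase list was called and 0 of the 31 others. Regrouping the real 4 h libraries gave up to 12 lists, so false list calls are not bounded. Sequence variants were not analysed here.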

Results

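SET2 is an established human megakaryoblastic line from a myeloproliferative neoplasm whose growth depends on JAK2 signalling. Poly(A) RNA was sequenced in 24 libraries that fall into 8 groups of 3. The groups are naive cells, 4 persistent lines kept in a type I JAK inhibitor (BMS911543, CYT387, INC424 or SAR302503), and naive cells given INC424 for 4 h, INC424 for 48 h or the vehicle DMSO for 4 h. INC424 is ruxolitinib, CYT387 is momelotinib and SAR302503 is fedratinib, while BMS911543 is a JAK2-selective inhibitor. The labels give no concentrations. Each library held 21770721 to 36160750 reads assigned to genes. Levels are mean normalised read counts ± SD over the 3 libraries of a group (n = 3 throughout, except 12 where the 4 lines are pooled), and changes are fitted log2 differences. A gene is said to rise, fall or change only where it passed the test, and a list named without a p passed with the preset and with an estimated correlation between genes. Labels do not say if replicates were separate cultures, so p-values measure spread within groups, not between lines.

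Library 2 of the CYT387 persistent line stood apart from the other 23. Marker genes of squamous epithelium (10 genes) and of stroma, vessel and macrophages (10 genes) took 0.613% and 0.825% of its reads. In that library TGFBI, a matrix protein, reached 140037 and KRT5, a basal keratin, 64415, against means of 9.64 and 201 in libraries 1 and 3 of the line. The squamous set took 0.113% of reads in SAR302503 persistent library 3, 0.0240% in INC424 48 h library 3, 0.0239% in INC424 persistent library 2 and at most 0.0176% in the other 20. Changes of the CYT387 line against naive cells, and the lists in which it differed from other lines, are therefore also given without its library 2. All fits share 1 estimate of the spread, so this library also affects the number of calls in comparisons it is not part of, and the alternatives without it, or without it and the other 3 libraries named here, were chosen after seeing the data.

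**Figure D1:**
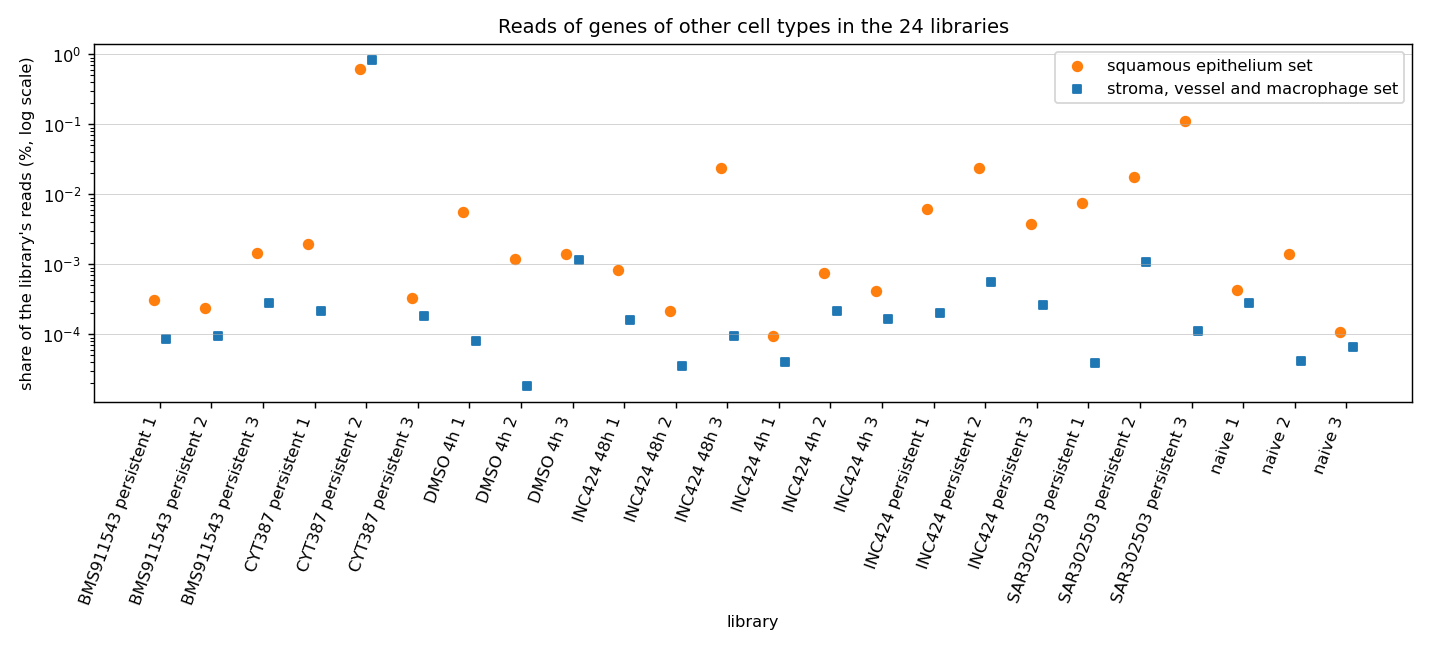
Share of reads (%, log axis) taken by 10 squamous epithelial and 10 stromal, vessel and macrophage marker genes in each of the 24 libraries. CYT387 persistent library 2 holds 0.613% and 0.825%, and SAR302503 persistent library 3 holds 0.113% of squamous markers.

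After 4 h of INC424 several JAK-STAT target genes of naive cells fell. SOCS3, a STAT-induced brake on the pathway, was 291 ± 10.9 with INC424 and 3165 ± 465 with DMSO (log2 -3.43). CISH, another such brake, was 226 ± 23.8 against 1249 ± 135 (log2 -2.46), and the kinase gene PIM1 was 1892 ± 29.2 against 9335 ± 706 (log2 -2.30). Of the JAK-STAT target genes, 11 of 15 fell (12 adjusted over the list alone). MAPK feedback genes moved the same way, with DUSP6 (11.2 ± 1.36 against 116 ± 14.7, log2 -3.26). Of the MAPK list 5 of 16 fell (7 fell and 1 rose, adjusted over the list alone, adjusted p = 0.072 with an estimated correlation, median log2 -1.46). EGR1, an immediate early transcription factor, fell from 991 ± 146 to 65.1 ± 20.7 (log2 -3.94), while its list did not pass (adjusted p = 0.068, and 0.024 to 0.0498 without DMSO library 1 or 2, INC424 4 h library 2 or the signature genes).

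Genes of ribosome biogenesis and heat shock fell and genes repressed by PI3K rose within the same 4 h. Of the MYC targets of ribosome biogenesis 16 of 30 fell (22 adjusted over the list alone), among them NIP7 (log2 -0.93) and PNO1 (log2 -0.94). Of the heat shock list 11 of 18 fell (13 adjusted over the list alone). The chaperone HSPA8 was 28894 ± 2913 against 89508 ± 3297 (log2 -1.64). Of the S phase list 4 of 25 fell (7 adjusted over the list alone). Of the cholesterol synthesis list 4 of 23 fell (10 fell and 2 rose, adjusted over the list alone). Of the FOXO and PI3K-repressed genes 9 of 17 rose (12 adjusted over the list alone), led by CCNG2 at 1148 ± 59.8 against 143 ± 19.0 (log2 3.00). Of the glycolysis and hypoxia list 11 of 28 rose (14 rose and 1 fell, adjusted over the list alone). Its members with the largest rises include BNIP3, a mitophagy receptor (log2 2.78), and PFKFB4 (log2 1.51). Of the BCL2 family 3 of 16 rose and 2 fell (3 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.54, median log2 -0.39). In it the pro-apoptotic genes BMF (log2 1.51) and BBC3 (log2 1.41) rose, and the anti-apoptotic genes BCL2L1 (log2 -1.24) and MCL1 (log2 -0.74) fell. Of the NF-kB list 1 of 19 rose and 5 fell (2 and 6 adjusted over the list alone, adjusted p = 0.12 with an estimated correlation, median log2 -0.31). SDK2 (log2 4.10) and ERVFRD-1 (log2 2.84) were among the largest rises, and ID1 (log2 -3.28) among the largest falls.

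In all 984 genes rose and 703 fell at 4 h in limma, of 20154 tested. 9 of the 32 lists passed with the preset correlation and 7 with an estimated one. With upper-quartile scaling the counts were 669 and 752. The count was 3316 without CYT387 persistent library 2, 4259 without the 4 libraries richest in epithelial RNA, and 930 to 1109 when any 1 of the 6 libraries compared was left out.

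After 48 h of INC424 the cells held less RNA of the S phase programme and more of several erythroid genes. Of the S phase list 23 of 25 fell (24 adjusted over the list alone), among them GINS1 (255 ± 12.8 against 975 ± 78.7, log2 -1.93) and CCNE2 (129 ± 19.5 against 462 ± 58.4, log2 -1.83). Of the G2 and M phase list 17 of 24 fell (17 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation, median log2 -0.55). Of the MYC targets of ribosome biogenesis 28 of 30 fell (29 adjusted over the list alone). Of the ATF4 and amino acid response list 3 of 25 rose and 16 fell (4 and 16 adjusted over the list alone). PSAT1 and ASNS, enzymes of serine and asparagine synthesis, were 346 ± 51.0 and 256 ± 61.2 against 3571 ± 146 and 2011 ± 107 (log2 -3.37 and -2.99). Of the erythroid list 14 of 21 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 0.31 with an estimated correlation, median log2 1.43). ALAS2, the enzyme that starts haem synthesis in red cells, was 8634 ± 233 against 1056 ± 115 (log2 3.04), and the anion exchanger gene SLC4A1 was 426 ± 29.3 against 50.4 ± 4.70 (log2 3.06).

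Of the JAK-STAT targets at 48 h 1 of 15 rose and 10 fell (1 and 10 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation, median log2 -0.98). Of the MAPK list 8 of 16 fell (8 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation, median log2 -1.22). ETV4, a transcription factor induced by ERK, was among the largest falls at 56.5 ± 35.6 against 1361 ± 208 (log2 -4.73). Of the FOXO and PI3K-repressed genes 12 of 17 rose (12 adjusted over the list alone), among them PIK3IP1 (log2 3.85) and S1PR1 (log2 3.01). Among the largest rises were GCGR (153 ± 10.1 against 2.14 ± 1.85, log2 5.89, and 5.20 without DMSO library 2) and TP53INP1 (2553 ± 213 against 62.4 ± 10.7, log2 5.34). TP53INP1 is a p53 target. Of the JAK, STAT and cytokine receptor list 10 of 27 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 0.078 with an estimated correlation, median log2 0.32), including JAK2 itself at 4633 ± 124 against 2569.8 ± 192 (log2 0.85). In naive cells JAK2 was 3958. Of the MHC class I list 7 of 14 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.21 with an estimated correlation, median log2 0.48). Of the ABC drug transporters 4 of 7 rose (5 adjusted over the list alone, adjusted p = 0.078 with an estimated correlation, median log2 0.79). Of the cytosolic ribosomal proteins 14 of 29 rose (18 adjusted over the list alone, adjusted p = 0.36 with an estimated correlation, median log2 0.54). Of the oxidative phosphorylation list 2 of 29 rose and 10 fell (2 and 10 adjusted over the list alone, adjusted p = 0.33 with an estimated correlation, median log2 -0.26). Of the heat shock list 10 of 18 fell (11 adjusted over the list alone, adjusted p = 0.17 with an estimated correlation, median log2 -0.45).

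In all 3543 genes rose and 3297 fell at 48 h, and 14 of the 32 lists passed with the preset correlation and 4 with an estimated one. The vehicle control is of 4 h, so duration in vehicle is not matched. Against naive cells 4039 genes changed, of which 2337 are among those called against DMSO.

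Set against 4 h directly, some lists that moved at 4 h of INC424 were moved further at 48 h and others less. There is no vehicle group of 48 h, so exposure time cannot be told apart from time in culture. Of the JAK-STAT targets 8 of 15 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 0.21 with an estimated correlation, median log2 0.47). Of the 11 targets that fell at 4 h, 7 were higher at 48 h than at 4 h, and 8 were still below DMSO. S phase genes fell further (21 of 25 fell, 24 adjusted over the list alone). The G2 and M phase genes (20 of 24 fell, 23 adjusted over the list alone) and the ATF4 list (1 of 25 rose and 16 fell, 2 and 19 adjusted over the list alone) fell between 4 h and 48 h, after 0 and 2 of their members had fallen at 4 h. Of the cholesterol synthesis list, low at 4 h, 8 of 23 rose and 1 fell (10 and 1 adjusted over the list alone). Of the erythroid list 10 of 21 rose (13 rose and 1 fell, adjusted over the list alone, adjusted p = 0.19 with an estimated correlation, median log2 1.02). Of the glycolysis and hypoxia list 1 of 28 rose and 9 fell (1 and 10 adjusted over the list alone, adjusted p = 0.071 with an estimated correlation, median log2 -0.33). Of the replication-dependent histones, listed as a sign of poly(A) selection, 4 of 11 rose (5 adjusted over the list alone, adjusted p = 0.11 with an estimated correlation, median log2 0.89). Changes against the shared DMSO libraries correlated across genes at r = 0.65, where simulated unchanged groups gave 0.50 from the shared control alone. Genes are not independent replicates. Of the genes that changed at 4 h, 879 rose and 597 fell at both times, 8 rose then fell and 1 fell then rose. In all 1417 genes were higher and 1550 lower at 48 h, and 15 of the 32 lists passed with the preset correlation and 4 with an estimated one. The count was 5073 without CYT387 persistent library 2, 5206 without the 4 libraries richest in epithelial RNA, 1907 without INC424 48 h library 1 and 1810 without INC424 4 h library 3.

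**Figure D2:**
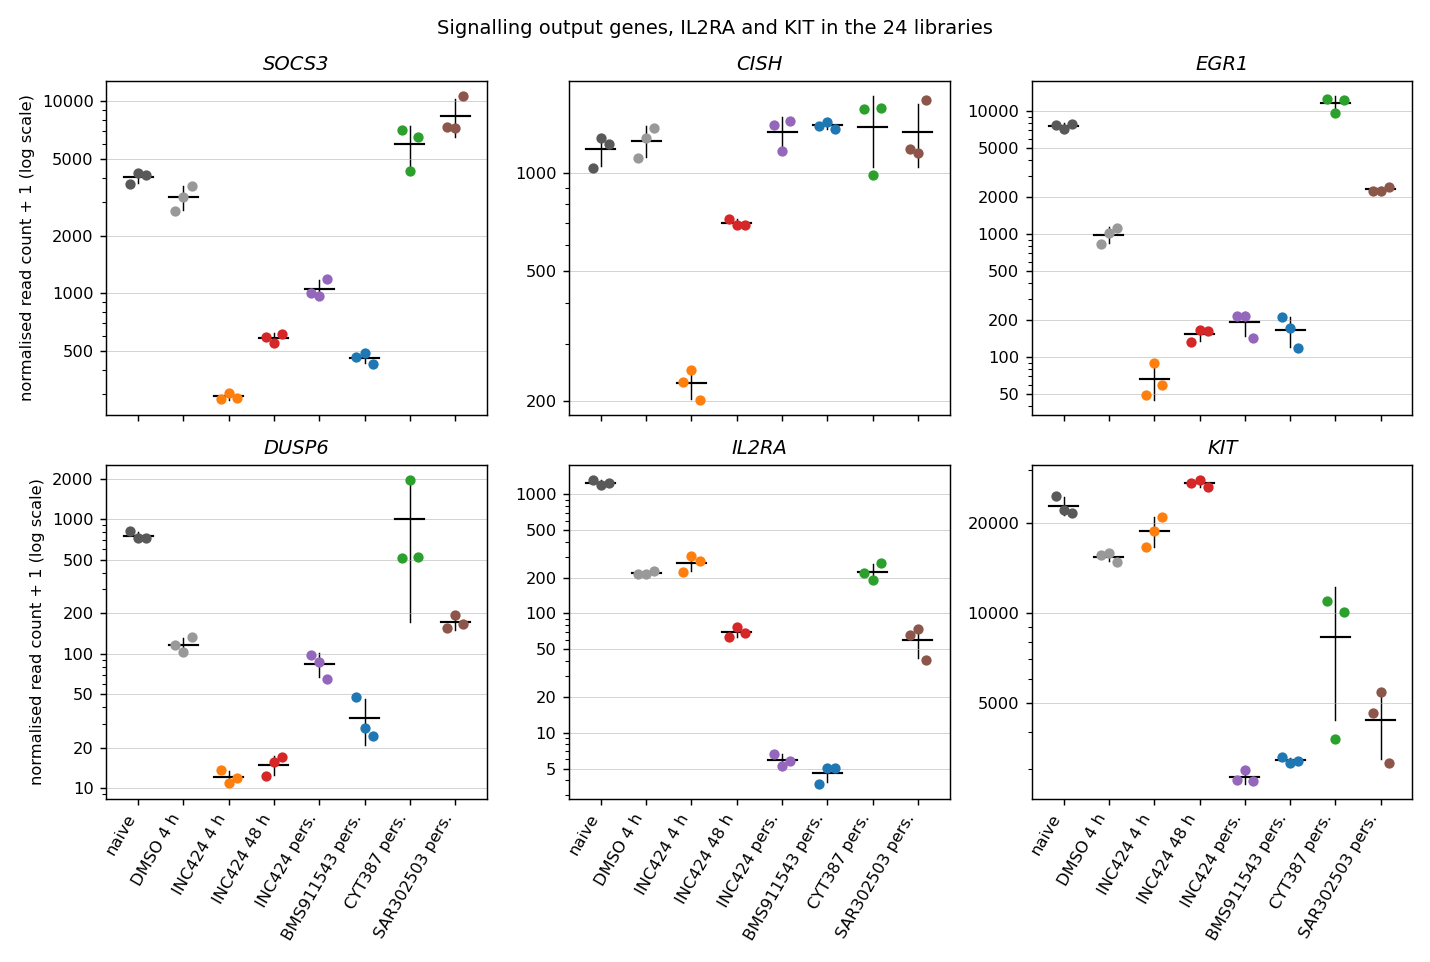
Normalised read counts plus 1 (log axis) of SOCS3, CISH, EGR1, DUSP6, IL2RA and KIT in each library of the 8 groups, with points for libraries, lines for means and bars for SD (n = 3). SOCS3 is 291 at 4 h of INC424 against 3165 with DMSO. The genes were picked for the plot after their values were seen.

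The mean of the 4 lines against naive asks how cells that persist in a type I inhibitor differ from naive cells. Several growth factor and cytokine receptors fell: IL2RA, a STAT5 target and receptor subunit, was 3.61, 223, 4.89 and 59.3 in the BMS911543, CYT387, INC424 and SAR302503 lines against 1249.6 ± 61.7 in naive cells (mean log2 -5.69). KIT, the stem cell factor receptor, was 3212, 8286, 2818 and 4391 in the same order against 22816 ± 1619 (log2 -2.46), and the shared beta chain CSF2RB was 11772 ± 5195 over 12 libraries against 40399.7 ± 7035 (log2 -1.86). Of the JAK, STAT and cytokine receptor list 2 of 27 rose and 10 fell (2 and 13 adjusted over the list alone). JAK2 was 6539, 2388, 3865 and 4136 against 3958 ± 368, and the mean of the lines did not pass. Of the granulocyte and monocyte list 8 of 17 fell (8 adjusted over the list alone), including CD33 (log2 -2.30) and CSF3R (log2 -2.13). Of the endoplasmic reticulum chaperones 11 of 19 fell (11 adjusted over the list alone). Of the ATF4 and amino acid response list 1 of 25 rose and 17 fell (3 and 17 adjusted over the list alone), but its medians in the lines, in the same order, were -1.54, -0.41 (-0.25 without library 2), 0.30 and -0.43, so INC424 went the other way. Of the S phase list 9 of 25 rose (11 adjusted over the list alone), with medians of 0.03, 0.03 (0.17 without library 2), 0.60 and 0.48, so the rise rests mainly on INC424 and SAR302503. Naive cells given DMSO, without inhibitor, also moved these ways against naive, with medians (DMSO, then the mean of the lines) of -0.34 and -0.26 for the JAK, STAT and receptor list, -1.12 and -0.48 for the ATF4 list and 0.47 and 0.25 for S phase, and IL2RA at 218 ± 7.35. These list shifts thus also occur without inhibitor. IL2RA fell further except in CYT387, and KIT (at least 14807 with DMSO) in each line.

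Some erythroid and G2 and M phase genes were higher in the mean of the lines. Of the erythroid list 12 of 21 rose and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 0.14 with an estimated correlation, median log2 1.45). HBA2, whose reads cannot be fully told from those of its near copy HBA1, was 12909, 1741, 6450.2 and 2098 in the 4 lines against 196 ± 25.1 (log2 4.28), and the embryonic globin HBE1 6104, 885, 24569 and 13228 against 690.3 ± 165 (log2 3.14). Of the G2 and M phase list 16 of 24 rose (18 adjusted over the list alone, adjusted p = 0.10 with an estimated correlation, median log2 0.43), led by CDC20 (log2 1.05). The erythroid and the G2 and M phase list did not pass in the CYT387 line alone (adjusted p = 0.41 and 0.25, and 2.4e-05 and 0.032 without its library 2), with median log2 changes of -0.03 and 0.10 there, and 0.86 and 0.20 without that library. Of the oxidative phosphorylation list 10 of 29 rose (11 adjusted over the list alone, adjusted p = 0.11 with an estimated correlation, median log2 0.33). JAK-STAT targets were lower in part (1 of 15 rose and 7 fell, 1 and 7 adjusted over the list alone, adjusted p = 0.33 with an estimated correlation, median log2 -0.54), as were MAPK output genes (7 of 16 fell, 7 adjusted over the list alone, adjusted p = 0.29 with an estimated correlation, median log2 -0.47). In the lines the medians were -0.58, 0.18 (0.42 without library 2), -0.86 and 0.16 for JAK-STAT targets and -1.22, 0.78 (-0.20 without library 2), -1.02 and -0.11 for MAPK output. For the MHC class II list 6 of 10 fell (8 fell and 1 rose, adjusted over the list alone, adjusted p = 0.14 with an estimated correlation, median log2 -0.90), and the single lines went opposite ways (0.32, 2.13, -2.13 and -3.63). Of the NRF2 list 3 of 15 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.54 with an estimated correlation, median log2 0.47). Of the MHC class I list 5 of 14 fell (5 adjusted over the list alone, adjusted p = 0.40 with an estimated correlation, median log2 -0.24; adjusted p = 0.07 with the preset correlation without CYT387 persistent library 2). Among the largest rises were the secreted binding protein IGFBP5 (log2 5.89, and 4.61 with DMSO) and MAL, which had 3 reads over the naive libraries and was 555-fold higher (95% counting interval 189.7 to 2691). The fitted log2 was 6.84, and 7.52 without naive library 3. MAL was 1353, 38.8, 828 and 26.3 in the 4 lines. Among the largest falls were TCN1 (12.4 ± 20.6 against 799 ± 203, log2 -7.32) and ADCYAP1 (476 ± 489.9 against 22205 ± 971, log2 -7.18), followed by DHRS9 (log2 -6.64), PRG2 (log2 -6.52) and ABCB11 (log2 -6.44).

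In all 1974 genes were higher and 2422 lower in the mean of the lines, and 13 of the 32 lists passed with the preset correlation and 5 with an estimated one. 260 genes rose and 466 fell in each of the 4 lines. Simulated unchanged groups gave 0 such genes in each of 20 draws, but few are called without effects. Independent lines would give 2.03 and 4.22, but all share naive cells, whose part was not tested. Across genes the changes of a pair of lines correlated at r = 0.33 (BMS911543 and CYT387) to 0.63 (INC424 and SAR302503). The shared naive libraries alone gave r = 0.50 in simulation, with covariances of 0.14 against 0.42 to 0.76 observed. The share of genes with 1 sign in all 4 lines, 38.6%, did not exceed the 39.9% of the simulation. Without the 4 libraries the mean gave 6763 genes and 1108 were alike, or 2771 and 396 in a fit of the compared groups.

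**Figure D3:**
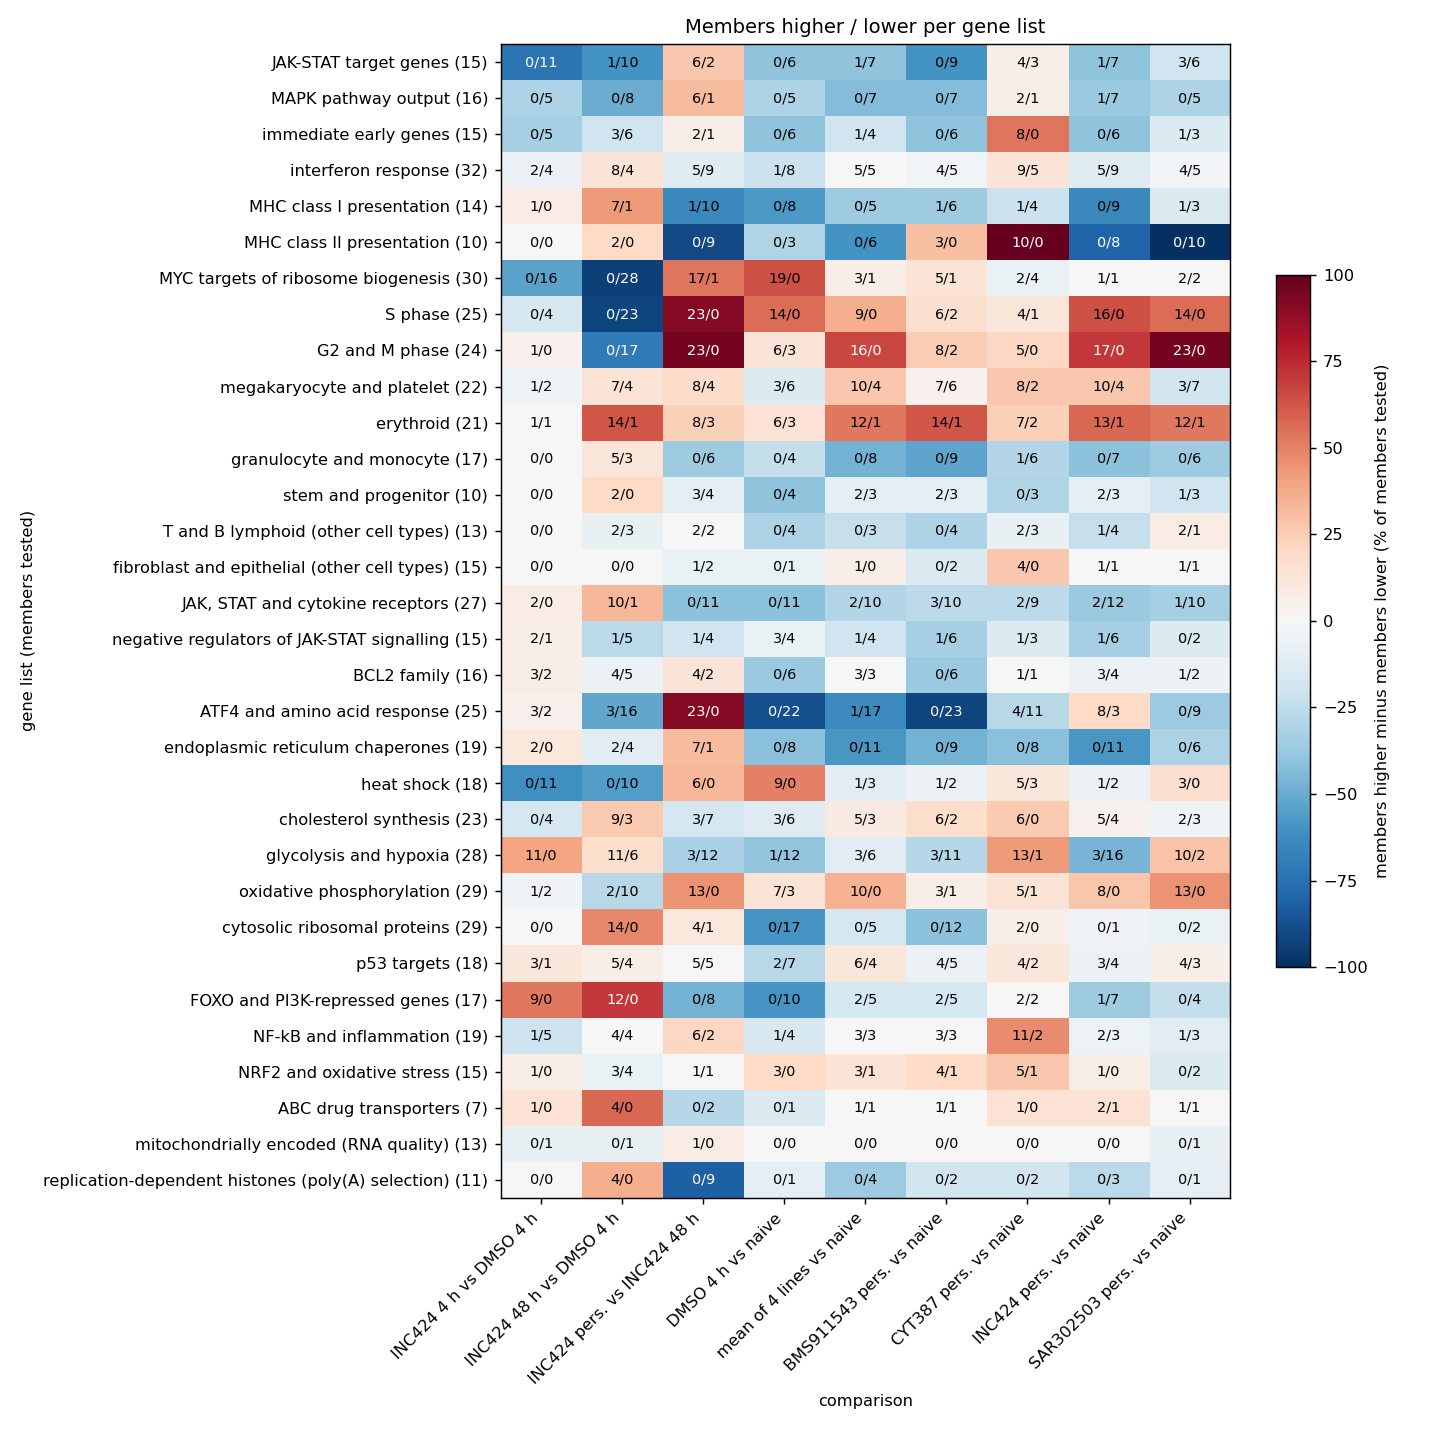
Members of the 32 gene lists that were higher or lower in 9 comparisons (numbers in cells), with colour for higher minus lower in % of members tested. MHC class II genes are 10 higher in the CYT387 line and 10 lower in the SAR302503 line, of 10 tested.

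The BMS911543 persistent line held less RNA of the ATF4 and amino acid response list, of which 23 of 25 fell (23 adjusted over the list alone). PHGDH, which starts serine synthesis, was 957 ± 87.7 against 15062 ± 2095 in naive cells (log2 -3.97), and STC2 and ALDH1L2 changed by log2 -4.11 and -4.07. JAK-STAT targets were lower in part, with SOCS3 at 461 ± 28.4 against 4021 ± 266 (log2 -3.12) and PIM1 at 5868 ± 733 against 33429.7 ± 930.1 (log2 -2.52). In that list 9 of 15 fell (9 adjusted over the list alone, adjusted p = 0.11 with an estimated correlation, median log2 -0.58). Of the 11 targets that fell at 4 h of INC424, 8 were below naive in this line. EGR1 was 167 ± 46.1 against 7592 ± 374 (log2 -5.53). Of the immediate early genes 6 of 15 fell (6 fell and 1 rose, adjusted over the list alone, adjusted p = 0.11 with an estimated correlation, median log2 -0.40). That list also missed the threshold with the preset correlation with TMM scaling, without BMS911543 library 3, naive library 2 or 3 or CYT387 library 2, and without the 4 libraries richest in epithelial RNA (adjusted p = 0.052 to 0.12). JAK2 was 6539 ± 179 against 3958 ± 368, log2 0.73, and its call ended (adjusted p = 0.0504 to 0.066) when any 1 of BMS911543 libraries 1, 2 and 3 or naive libraries 2 and 3 was left out. Of the granulocyte and monocyte list 9 of 17 fell (9 adjusted over the list alone). Of the JAK, STAT and receptor list 3 of 27 rose and 10 fell (3 and 10 adjusted over the list alone). Of the erythroid list 14 of 21 rose and 1 fell (15 and 1 adjusted over the list alone, adjusted p = 0.11 with an estimated correlation, median log2 1.47). Of the MAPK list 7 of 16 fell (8 adjusted over the list alone, adjusted p = 0.11 with an estimated correlation, median log2 -1.22). Of the glycolysis and hypoxia list 3 of 28 rose and 11 fell (3 and 12 adjusted over the list alone, adjusted p = 0.20 with an estimated correlation, median log2 -0.35). Of the 13 mitochondrially encoded genes, a sign of RNA quality, 0 rose (0 adjusted over the list alone), while their list was called higher (adjusted p = 0.04, 0.58 with an estimated correlation, median log2 0.54). It missed the threshold without BMS911543 library 1 or 2 or naive library 2 or 3 (adjusted p = 0.051 to 0.12). Against naive, the medians with DMSO and in this line were -1.12 and -1.54 for the ATF4 list, -0.34 and -0.54 for the JAK, STAT and receptor list and -0.97 and -0.40 for immediate early genes, and with DMSO 4 of the 11 targets were below naive and PIM1 was at log2 -1.84 and EGR1 at -2.95. Of the genes with the largest changes, ADCYAP1, a neuropeptide gene, was 18.6 ± 14.8 against 22205 ± 971, log2 -10.40, and ITLN1 was 1853 ± 82.4 against 14.6 ± 11.8, log2 7.15. In all 2089 genes rose and 2866 fell, and 16 of the 32 lists passed with the preset correlation and 3 with an estimated one. The count was 8015 without the 4 libraries richest in epithelial RNA.

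The CYT387 persistent line held more RNA of MHC class II and immediate early genes than naive cells. Of the MHC class II list 10 of 10 rose (10 adjusted over the list alone), and 9 of 10 rose without library 2, with median log2 changes of 2.13 and 1.66. HLA-DRA was 11037 ± 2174 against 2319 ± 334, log2 2.24, and 2.09 without library 2. HLA-DPB1 was 2566 ± 1827 against 396 ± 61.6, log2 2.48, and 1.94 without library 2. Of the immediate early genes 8 of 15 rose (8 adjusted over the list alone), and 9 without library 2. FOS, an AP-1 subunit, was 4227 ± 5101 against 82.3 ± 8.70, log2 4.94, and 3.95 without library 2, and FOSB was at log2 3.87, and 2.90 without library 2 (adjusted p = 0.065 in a fit of the 6 libraries alone). Of the NF-kB list 11 of 19 rose and 2 fell (13 and 3 adjusted over the list alone), and 10 rose and 3 fell without library 2. BIRC3 was 1185 ± 839 against 121 ± 32.4, log2 3.09, and 2.55 without library 2. Of the JAK-STAT targets 4 of 15 rose and 3 fell (6 and 4 adjusted over the list alone; 6 rose and 1 fell without library 2), and the list did not pass the test (adjusted p = 0.81), though it was called higher without the 4 libraries richest in epithelial RNA (adjusted p = 0.041). Its median log2 was 0.18, and 0.42 without library 2. IL2RA was lower (log2 -2.49, -2.38 without library 2) and ID1 higher (log2 1.78, 1.49 without library 2). With DMSO IL2RA was at 218 ± 7.35 (log2 -2.52 against naive), so its fall in this line is no larger than the gap between the controls. JAK2 was 2388 ± 974 against 3958 ± 368, log2 -0.83, and -0.42 without library 2. Its call ended without library 2 (adjusted p = 0.059) and without naive library 1 (adjusted p = 0.053). IGFBP5 was 20067 ± 608 against 39.9 ± 11.1, log2 8.97, and 8.96 without library 2 (log2 4.61 with DMSO), and KCNA2, a potassium channel gene with 0 reads in the naive libraries, was at least 485-fold higher (fitted log2 8.92, 9.31 without library 2).

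Glycolysis and hypoxia genes rose in part in the CYT387 line (13 of 28 rose and 1 fell, 14 and 2 adjusted over the list alone, adjusted p = 0.15 with an estimated correlation, median log2 0.34; 10 rose and 1 fell without library 2). Of the megakaryocyte and platelet list 8 of 22 rose and 2 fell (8 and 3 adjusted over the list alone, adjusted p = 0.51 with an estimated correlation, median log2 0.38 and 0.73 without library 2; 12 rose and 3 fell without library 2), which also missed the threshold with the preset correlation without library 1 or 3 (adjusted p = 0.078 and 0.079). PPBP, a platelet chemokine, was 1129 ± 510.2 against 15.2 ± 6.55, log2 6.06, and 6.52 without library 2. Of the fibroblast and epithelial list 4 of 15 rose (6 adjusted over the list alone, adjusted p = 0.69 with an estimated correlation, median log2 2.01 and 0.37 without library 2), the list of the cell types whose markers fill library 2, and 2 rose and 0 fell without it (adjusted p = 0.67 with the preset correlation, 0.79 without the 4 libraries richest in epithelial RNA and 0.95 without the signature genes of library 2). The granulocyte and monocyte list and the histones did not pass (adjusted p = 0.085 and 0.28) and were called lower without library 2 (adjusted p = 0.0043 and 0.032). TCN1 was 35.9 ± 32.6 against 799 ± 203, log2 -5.78, and -3.86 without library 2, -6.61 without library 1 and -6.87 without library 3 (adjusted p = 0.11 in a fit of the 6 libraries alone), and PRG2 was 61.7 ± 36.8 against 1613 ± 91.3, log2 -4.94, and -4.27 without library 2. In all 2262 genes rose and 2239 fell, and 10 of the 32 lists passed with the preset correlation and 3 with an estimated one. 3659 genes changed without library 2, 522 in a fit of the 6 libraries alone, and the lists passing rose to 16 without naive library 1.

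The INC424 persistent line combined low MHC class II genes and lower genes of the JAK, STAT and receptor list with more proliferation genes. CIITA, the master regulator of MHC class II, was 59.8 ± 13.7 against 651 ± 71.9, log2 -3.44, the invariant chain CD74 was 1309.9 ± 193 against 7638 ± 64.5, log2 -2.55, and in the list 8 of 10 fell (8 adjusted over the list alone). Of the S phase list 16 of 25 rose (19 adjusted over the list alone). Of the G2 and M phase list 17 of 24 rose (23 adjusted over the list alone), led by CDC20 at 7059.8 ± 1026 against 2571 ± 252 (log2 1.45). KIT was 2818 ± 137 against 22816 ± 1619, log2 -3.02. Of the JAK, STAT and receptor list 2 of 27 rose and 12 fell (2 and 12 adjusted over the list alone), with IL6R at log2 -4.33. Of the JAK-STAT targets 1 of 15 rose and 7 fell (1 and 8 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation, median log2 -0.86). SOCS3 was 1057 ± 120.4 against 4021 ± 266, log2 -1.93. Of the immediate early genes 6 of 15 fell (6 adjusted over the list alone). Of the granulocyte and monocyte list 7 of 17 fell (7 adjusted over the list alone). Of the endoplasmic reticulum chaperones 11 of 19 fell (11 adjusted over the list alone). Of the glycolysis and hypoxia list 3 of 28 rose and 16 fell (3 and 18 adjusted over the list alone). Of the ATF4 list 8 of 25 rose and 3 fell (9 and 3 adjusted over the list alone, adjusted p = 0.28 with an estimated correlation, median log2 0.30), with the amino acid transporter gene SLC7A5 at 14439.8 ± 530.2 against 5741 ± 200.1 (log2 1.33) and STC2 lower (log2 -3.26). Of the erythroid list 13 of 21 rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 0.066 with an estimated correlation, median log2 2.09), with HBE1 at 24569 ± 2115 against 690.3 ± 165 (log2 5.17). Against naive, the medians with DMSO and in this line were 0.47 and 0.60 for S phase, -0.34 and -0.30 for the JAK, STAT and receptor list and -0.97 and -0.58 for immediate early genes, so these shifts also occur without inhibitor. In all 2006 genes rose and 2525 fell, or 2594 and 2041 with upper-quartile scaling, which moved the median gene by 0.10 log2. 17 of the 32 lists passed with the preset correlation and 8 with an estimated one. The count was 7041 without the 4 libraries richest in epithelial RNA.

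The SAR302503 persistent line held little RNA of several MHC class II genes. HLA-DRA was 144 ± 25.3 against 2319 ± 334, log2 -4.01, HLA-DRB1 was 86.9 ± 31.2 against 1748 ± 200.1, log2 -4.36, and 10 of 10 fell (10 adjusted over the list alone). Proliferation genes were higher: of the S phase list 14 of 25 rose (16 adjusted over the list alone), with PCNA at log2 0.97. Of the G2 and M phase list 23 of 24 rose (24 adjusted over the list alone), with CCNB1 at 2433 ± 95.9 against 1022 ± 228 (log2 1.27). Of the oxidative phosphorylation list 13 of 29 rose (17 adjusted over the list alone). Of the JAK, STAT and receptor list 1 of 27 rose and 10 fell (1 and 11 adjusted over the list alone), which missed the threshold with the preset correlation without the 4 libraries richest in epithelial RNA (adjusted p = 0.057). LIF, a cytokine gene under STAT control, was 62.3 ± 26.9 against 1085 ± 263, log2 -4.15, and IL2RA was 59.3 ± 17.6 against 1249.6 ± 61.7, log2 -4.42, whereas ID1 rose (log2 1.68), as did SOCS3 (8401 ± 1904 against 4021 ± 266, log2 1.04). Of the JAK-STAT targets 3 of 15 rose and 6 fell (3 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.32, median log2 0.16). Platelet genes fell in part (3 of 22 rose and 7 fell, 5 and 8 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation, median log2 -0.38), among them VWF at 5.38 ± 6.31 against 358 ± 13.1 (log2 -6.49, -5.49 without library 1 and -7.35 without library 3), and the list missed the threshold with the preset correlation with a pseudocount of 10, with the replicate block, without SAR302503 library 1 or 2 or CYT387 library 2, and without the 4 libraries richest in epithelial RNA (adjusted p = 0.057 to 0.14). In the erythroid list 12 of 21 rose and 1 fell (14 and 1 adjusted over the list alone, adjusted p = 0.20 with an estimated correlation, median log2 1.19). Of the glycolysis and hypoxia list 10 of 28 rose and 2 fell (10 and 2 adjusted over the list alone, adjusted p = 0.20 with an estimated correlation, median log2 0.23; adjusted p = 0.052 with the preset correlation without library 3 and 0.095 without the 4 libraries). Of the ATF4 list 9 of 25 fell (11 adjusted over the list alone, adjusted p = 0.20 with an estimated correlation, median log2 -0.43). The mitochondrially encoded list did not pass (adjusted p = 0.094, median log2 -0.53) and was called lower without SAR302503 library 2 or 3, naive library 2 or 3, or the 4 libraries (adjusted p = 0.032 to 0.049). Against naive, the medians with DMSO and in this line were 0.47 and 0.48 for S phase, -0.34 and -0.06 for the JAK, STAT and receptor list and -1.12 and -0.43 for the ATF4 list, so these list shifts also occur without inhibitor. With DMSO LIF was at log2 -1.09 and IL2RA at -2.52, smaller falls than in this line. WNT5A, with 1 read in the naive libraries, was 1307-fold higher (95% counting interval 234 to 51669), and ATP10A, with 0 reads in the line, was at least 255-fold lower. The keratin gene KRT14 (log2 9.29) ranks among the largest rises and moves with the squamous markers of library 3, which holds 10072 counts of it. Without library 3 KRT14 was at log2 7.96 (adjusted p = 0.011; 10.15 without library 1, 10.11 and 8.61 without naive library 1 and 3). In all 1754 genes rose and 2134 fell, or 1240 and 2332 with upper-quartile scaling. 10 of the 32 lists passed with the preset correlation and 5 with an estimated one. The count was 6090 without CYT387 persistent library 2, 6875 without the 4 libraries richest in epithelial RNA and 2395 in a fit of the 6 libraries alone.

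**Figure D4:**
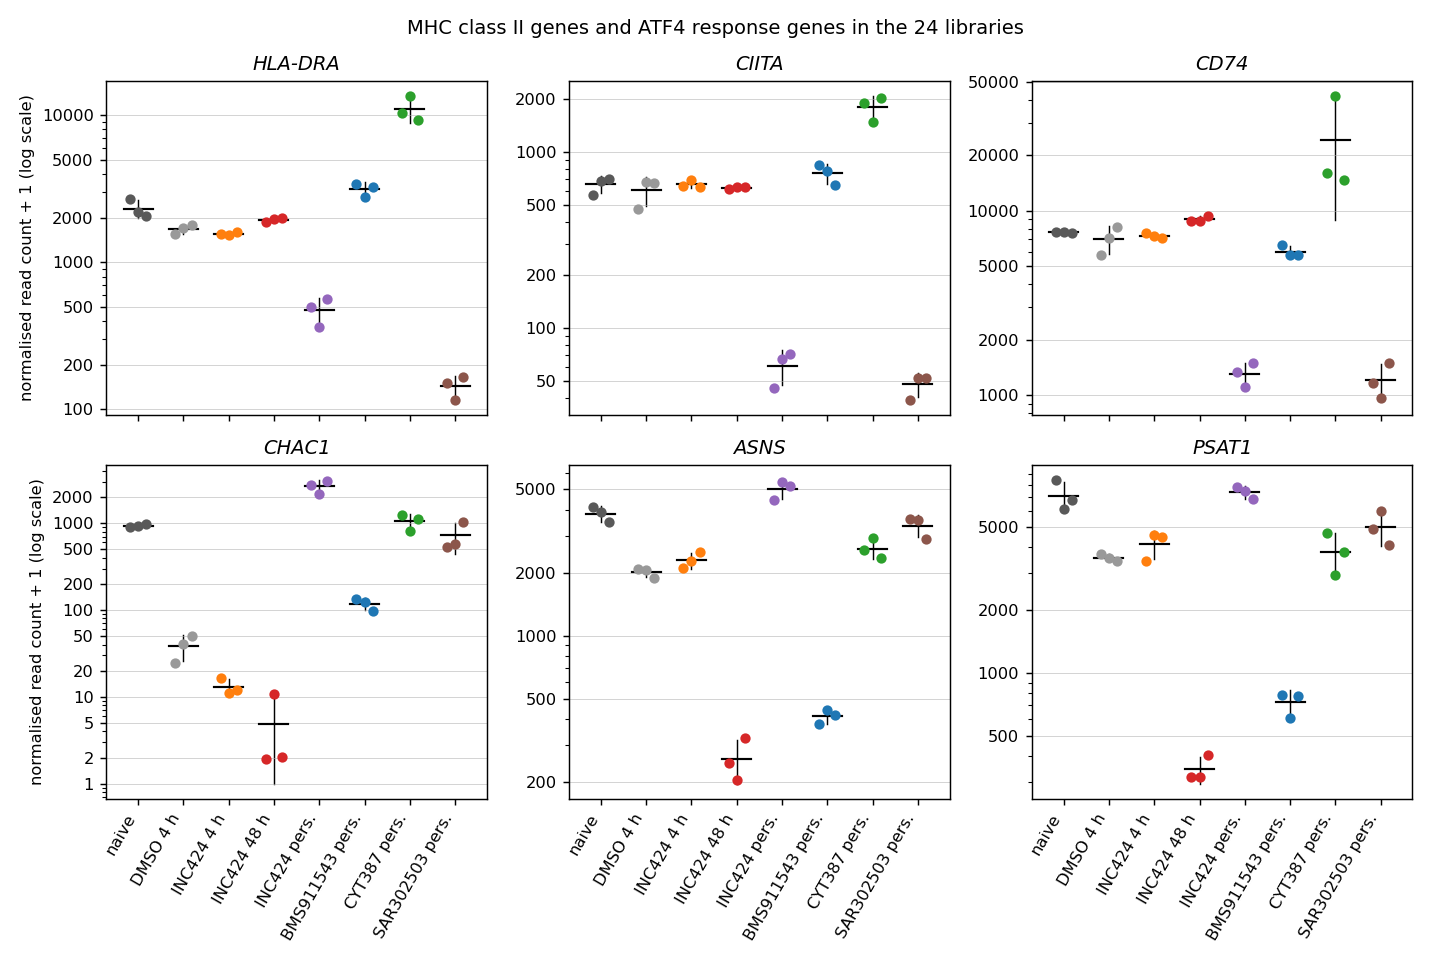
Normalised read counts plus 1 (log axis) of HLA-DRA, CIITA, CD74, CHAC1, ASNS and PSAT1 in each library of the 8 groups, with points for libraries, lines for means and bars for SD (n = 3). HLA-DRA is 11037 in the CYT387 line and 144 in the SAR302503 line against 2319 in naive cells. The genes were picked for the plot after their values were seen.

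The 4 lines were also compared with each other, since inhibitors of 1 class need not leave cells in 1 state. Culture concentrations cannot be matched. BMS911543 and INC424 lines differed in the ATF4 list, where 23 of 25 were lower (23 adjusted over the list alone) with BMS911543, and in MHC class II, where 10 of 10 were higher (10 adjusted over the list alone). PHGDH was 957 ± 87.7 against 16346 ± 3730.2, log2 -4.07, and HLA-DRA was 3159 ± 332 against 472 ± 102, log2 2.76. S phase genes were lower with BMS911543 (1 of 25 was higher and 14 were lower, 1 and 17 adjusted over the list alone), as were G2 and M phase genes (15 of 24 were lower, 18 were lower and 1 was higher, adjusted over the list alone, adjusted p = 0.12 with an estimated correlation, median log2 -0.58). The collagen gene COL11A1, with 3 reads in the BMS911543 line, was 2615-fold higher (95% counting interval 894 to 12682) with INC424. In all 1569 genes were higher and 1760 lower with BMS911543, and 9 of the 32 lists passed with the preset correlation and 3 with an estimated one. The count was 5425 without CYT387 persistent library 2, 5819 without the 4 libraries richest in epithelial RNA and 5995 in a fit of the 6 libraries alone.

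BMS911543 and SAR302503 lines differed in MHC class II and ATF4 genes: 10 of 10 were higher (10 adjusted over the list alone) for MHC class II and 19 of 25 were lower (19 adjusted over the list alone) for ATF4 with BMS911543. Glycolysis and hypoxia genes were lower with BMS911543 (1 of 28 was higher and 15 were lower, 1 and 17 adjusted over the list alone), as were S phase (16 of 25 were lower, 16 adjusted over the list alone) and granulocyte and monocyte genes (5 of 17 were lower, 5 adjusted over the list alone). Of the mitochondrially encoded genes 9 of 13 were higher (11 adjusted over the list alone, adjusted p = 0.31 with an estimated correlation, median log2 1.04). Of the lymphoid list 1 of 13 was higher and 5 were lower (2 and 6 adjusted over the list alone). The platelet chemokine PPBP, with 1 read in the SAR302503 line, was 1099.6-fold higher (95% counting interval 197 to 43468) with BMS911543. In all 2389 genes were higher and 2753 lower with BMS911543, or 3119 and 1859 with upper-quartile scaling (median gene moved by 0.14 log2), and 16 of the 32 lists passed with the preset correlation and 6 with an estimated one. 8209 genes differed without the 4 libraries richest in epithelial RNA. INC424 and SAR302503 lines differed in glycolysis and hypoxia genes, where 21 of 28 were lower (23 were lower and 1 was higher, adjusted over the list alone) with INC424, and in the ATF4 list, where 17 of 25 were higher (17 adjusted over the list alone). PFKFB4, a regulator of glycolysis, was 433 ± 65.6 against 2722 ± 146, log2 -2.66. Megakaryocyte and platelet genes were higher with INC424 (11 of 22 were higher, 12 adjusted over the list alone, adjusted p = 0.071 with an estimated correlation, median log2 0.89). Of the mitochondrially encoded genes 1 of 13 was higher (1 adjusted over the list alone, adjusted p = 0.53 with an estimated correlation, median log2 0.59), a call that ended with the preset correlation without SAR302503 library 1 (adjusted p = 0.079). In all 1226 genes were higher and 1340 lower with INC424, or 1999 and 769 with upper-quartile scaling (median gene moved by 0.18 log2), and 12 of the 32 lists passed with the preset correlation and 2 with an estimated one. The count was 4519 without CYT387 persistent library 2, 6820 without the 4 libraries richest in epithelial RNA, 1662 without INC424 persistent library 1, 1693 without its library 3 and 1607 in a fit of the 6 libraries alone.

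The CYT387 line differed from each other line in immediate early and MHC class II genes, and its library 2 enters all 3 comparisons. Against BMS911543, the immediate early list had 10 of 15 members higher with CYT387 (10 adjusted over the list alone; 11 without library 2), and the MHC class II list 9 of 10 (9 adjusted over the list alone; 9 without library 2). With BMS911543, 19 of 25 were lower (22 adjusted over the list alone; 22 were lower without library 2) in the ATF4 list and 11 of 16 were lower (13 adjusted over the list alone; 1 was higher and 11 were lower without library 2) in the MAPK list. In the glycolysis and hypoxia list 19 of 28 were lower (19 adjusted over the list alone; 2 were higher and 19 were lower without library 2). In the NF-kB list 1 of 19 was higher and 11 were lower (1 and 12 adjusted over the list alone; 2 were higher and 11 were lower without library 2). In the lymphoid list 5 of 13 were lower (5 adjusted over the list alone; 4 were lower without library 2; adjusted p = 0.0504 with an estimated correlation, median log2 -0.97 and -0.59 without library 2). JAK2 was 6539 ± 179 against 2388 ± 974, log2 1.55, and 1.15 without library 2. ELAVL4, an RNA-binding protein gene with 0 reads in the BMS911543 line, was at least 1074-fold higher with CYT387 (fitted log2 of BMS911543 to CYT387 -9.62, and -10.44 without library 2). Set against INC424, with CYT387 9 of 15 were higher (9 adjusted over the list alone; 10 were higher without library 2) in the immediate early list and 10 of 10 were higher (10 adjusted over the list alone; 10 were higher without library 2) in MHC class II. In glycolysis and hypoxia 22 of 28 were higher (23 adjusted over the list alone; 23 were higher without library 2), and in S phase 16 of 25 were lower (17 adjusted over the list alone; 18 were lower without library 2). The fibroblast and epithelial list was called higher with CYT387 than with BMS911543 and INC424 (adjusted p = 0.0038 and 0.045) and was not without library 2 (adjusted p = 0.20 and 0.55), nor with an estimated correlation (adjusted p = 0.55 and 0.59). Set against SAR302503, with CYT387 11 of 15 were higher and 1 was lower (11 and 1 adjusted over the list alone; 11 were higher and 1 was lower without library 2) in the immediate early list and 10 of 10 were higher (10 adjusted over the list alone; 10 were higher without library 2) in MHC class II. In the NF-kB list 11 of 19 were higher and 2 were lower (12 and 2 adjusted over the list alone; 11 were higher and 2 were lower without library 2). In the platelet list 12 of 22 were higher and 1 was lower (12 and 1 adjusted over the list alone; 14 were higher and 1 was lower without library 2; adjusted p = 0.17 with an estimated correlation, median log2 1.34). Of the mitochondrially encoded genes 8 of 13 were higher (9 adjusted over the list alone; 3 were higher without library 2), whose list passed (adjusted p = 0.0068, 0.67 with an estimated correlation) and missed the threshold without library 2, without SAR302503 library 1 and without the 4 libraries (adjusted p = 0.064 to 0.14). In all 2879 genes were higher and 3454 lower with BMS911543 than with CYT387 (3758 and 2785 with upper-quartile scaling, median gene moved by 0.13 log2). CYT387 had 2776 higher and 2135 lower than INC424 (2215 and 3464 with upper-quartile scaling, median gene moved by -0.17 log2), and 2737 higher and 2568 lower than SAR302503. Of the 32 lists, 15, 14 and 10 passed with the preset correlation and 8, 8 and 4 with an estimated one. Without library 2 the counts were 6076, 4838 and 5323, and in fits of the 6 libraries alone, library 2 included, 1970, 1216 and 534.

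Chronic and acute exposure to 1 inhibitor were compared in the INC424 persistent line and the 48 h group. ATF4 and S phase genes, which fell at 48 h, were at higher levels in the persistent line, while the heat shock and MAPK lists did not pass (adjusted p = 0.28 and 0.051). With 8 alternatives, TMM scaling among them, the MAPK list was called higher (adjusted p = 0.016 to 0.045). Of the ATF4 and amino acid response list 23 of 25 were higher (23 adjusted over the list alone). CHAC1 was 2669 ± 450.3 against 3.88 ± 5.04, log2 9.58, and 10.39 without INC424 48 h library 2, and ASNS was 5012 ± 519 against 256 ± 61.2, log2 4.31. The controls of the line and the 48 h group differ in this list too, with a median log2 of -1.12 and CHAC1 at -4.67 for DMSO against naive, beside a median of 2.53 here, so exposure time is not isolated. S phase (23 of 25 were higher, 24 adjusted over the list alone) and G2 and M phase genes (23 of 24 were higher, 23 adjusted over the list alone) were higher, with AURKA at 3613 ± 380.0 against 1158 ± 101 (log2 1.64). Of the 11 JAK-STAT targets that fell at 4 h, 6 were higher and 1 lower than at 48 h. Over the whole list 6 of 15 were higher and 2 were lower (6 and 2 adjusted over the list alone, adjusted p = 0.39 with an estimated correlation, median log2 0.54). PIM2, a survival kinase gene, was 6945 ± 796 against 1740.0 ± 14.8, log2 1.99 (log2 -1.40 in DMSO relative to naive). MHC class II genes were lower in the persistent line (9 of 10 were lower, 9 adjusted over the list alone), as were genes of the JAK, STAT and receptor list (11 of 27 were lower, 11 were lower and 1 was higher, adjusted over the list alone), with KIT at 2818 ± 137 against 27144 ± 663 (log2 -3.27). Of the replication-dependent histones 9 of 11 were lower (9 adjusted over the list alone, adjusted p = 0.076 with an estimated correlation, median log2 -1.51). Of the MYC targets of ribosome biogenesis 17 of 30 were higher and 1 was lower (19 and 1 adjusted over the list alone, adjusted p = 0.19 with an estimated correlation, median log2 0.51). Of the oxidative phosphorylation list 13 of 29 were higher (13 adjusted over the list alone, adjusted p = 0.097 with an estimated correlation, median log2 0.45). EPB41L3, with 2 reads in the 48 h group, was 1937-fold higher (95% counting interval 536 to 16001), and NSG1 was 1.93 ± 1.75 against 763 ± 62.5, log2 -8.27, and -7.63 without INC424 persistent library 1.

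In all 2931 genes were higher and 3100 lower in the persistent line than at 48 h, and 11 of the 32 lists passed with the preset correlation and 5 with an estimated one. A fit of the 6 libraries alone gave 9335. The changes at 48 h (against DMSO) and in the line (against naive) share no library. Their r was -0.03 across 20154 genes, which are not independent replicates. Of genes called in each, 435 rose and 453 fell in both, 745 rose at 48 h but fell in the line, 484 the reverse. Independent changes would give 353, 413, 444 and 328. The controls differ, so opposed responses are not shown.

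Naive cells and DMSO-treated cells, the controls of the chronic and the acute groups, differed widely. Of the ATF4 and amino acid response list 22 of 25 fell (23 adjusted over the list alone) in DMSO relative to naive. CHAC1, a glutathione-degrading enzyme, was 37.4 ± 12.8 against 937 ± 39.8, log2 -4.67. Of the immediate early genes 6 of 15 fell (7 adjusted over the list alone), with EGR1 at 991 ± 146 against 7592 ± 374 (log2 -2.95). Of the FOXO and PI3K-repressed genes 10 of 17 fell (11 adjusted over the list alone), with CCNG2 at 143 ± 19.0 against 885 ± 98.4 (log2 -2.62). Genes of the JAK, STAT and receptor list fell (11 of 27 fell, 13 adjusted over the list alone), with STAT5B at log2 -1.09. Of 15 marker genes of other cell types 0 passed in the shared limma fit (0 at unadjusted p < 0.05, 0 with edgeR and 0 with DESeq2, which gave no adjusted p for 9 of them), while 6 were higher with DMSO in the fit without the 4 libraries richest in epithelial RNA. KRT14, at log2 3.74 in each, had an adjusted p of 0.17 and 0.0031. S phase genes rose (14 of 25 rose, 14 adjusted over the list alone). Of the MYC targets of ribosome biogenesis 19 of 30 rose (21 adjusted over the list alone, adjusted p = 0.058 with an estimated correlation, median log2 0.65). Of the cytosolic ribosomal proteins 17 of 29 fell (19 adjusted over the list alone, adjusted p = 0.25 with an estimated correlation, median log2 -0.57). In the JAK-STAT targets 6 of 15 fell (6 adjusted over the list alone, adjusted p = 0.29 with an estimated correlation, median log2 -0.35). Chaperone, glycolysis and hypoxia and MHC class I genes, low in some persistent lines, were lower with DMSO too (median log2 -0.28, -0.39 and -0.55, adjusted p = 0.14, 0.062 and 0.18 with an estimated correlation). In all 2307 genes were higher and 2942 lower with DMSO, or 3192 and 2099 with upper-quartile scaling (median gene moved by 0.13 log2), and 13 of the 32 lists passed with the preset correlation and 5 with an estimated one. The count was 8518 without the 4 libraries richest in epithelial RNA. Intervals and floors given for genes with few reads cover counting error only, since PCR reads carried no molecular identifiers.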

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

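The tests weighed here were chosen after the result was seen, except that of libraries run again for MHC class II, and so were 5 of the counts of splits; the other counts of splits were planned. Where the effects of a pair of treatments against their control differed, the difference itself was tested. By that test 2967 genes differed between INC424 at 48 h and at 4 h. Between lines 6333 genes differed for BMS911543 and CYT387, 3329 for BMS911543 and INC424, 5142 for BMS911543 and SAR302503, 4911 for CYT387 and INC424, 5305 for CYT387 and SAR302503, and 2566 for INC424 and SAR302503.

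Some lists had medians on opposite sides of naive in a pair of lines and passed the test of the difference, given as the median log2 difference with the preset correlation. Immediate early genes differed by -1.87 (adjusted p = 1.2e-06; -0.40 and 0.95 against naive) for BMS911543 and CYT387 and by 2.13 (adjusted p = 6.1e-08; 0.95 and -0.58 against naive) for CYT387 and INC424. MHC class II genes differed by 4.26 (adjusted p = 6.8e-19; 2.13 and -2.13 against naive) for CYT387 and INC424 and by 5.73 (adjusted p = 7.5e-22; 2.13 and -3.63 against naive) for CYT387 and SAR302503. ATF4 genes differed by -1.93 (adjusted p = 2.1e-33; -1.54 and 0.30 against naive) for BMS911543 and INC424, by -0.73 (adjusted p = 1.8e-05; -0.41 and 0.30 against naive) for CYT387 and INC424 and by 0.59 (adjusted p = 2.7e-10; 0.30 and -0.43 against naive) for INC424 and SAR302503. Glycolysis and hypoxia genes differed by -0.80 (adjusted p = 4.2e-07; -0.35 and 0.34 against naive) for BMS911543 and CYT387, by -0.78 (adjusted p = 2.0e-07; -0.35 and 0.23 against naive) for BMS911543 and SAR302503, by 0.90 (adjusted p = 1.3e-13; 0.34 and -0.46 against naive) for CYT387 and INC424 and by -0.90 (adjusted p = 1.4e-18; -0.46 and 0.23 against naive) for INC424 and SAR302503. Megakaryocyte and platelet genes differed by 1.34 (adjusted p = 1.4e-05; 0.38 and -0.38 against naive) for CYT387 and SAR302503 and by 0.89 (adjusted p = 4.3e-08; 0.43 and -0.38 against naive) for INC424 and SAR302503. With an estimated correlation the megakaryocyte and platelet list missed the threshold for CYT387 and SAR302503 (adjusted p = 0.17) and for INC424 and SAR302503 (adjusted p = 0.071), and the others passed. CYT387 medians against naive include library 2, and without it were 1.17 for immediate early, 1.66 for MHC class II, -0.25 for ATF4, 0.32 for glycolysis and hypoxia and 0.73 for megakaryocyte and platelet genes. Groups of 3 were not tested for outlying samples.

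A comparison of 3 libraries with 3 has 10 splits of the samples, too few for a share under 0.05. The real value and the highest of the other splits are given in that order for genes, then for lists. For the lines against naive these were 4955 and 0 genes, 16 and 11 lists (BMS911543), 4501 and 225 genes, 10 and 11 lists (CYT387), 4531 and 0 genes, 17 and 12 lists (INC424 persistent) and 3888 and 915 genes, 10 and 11 lists (SAR302503). For the acute groups and controls they were 1687 and 0 genes, 9 and 12 lists (INC424 4 h), 6840 and 0 genes, 14 and 15 lists (INC424 48 h), 2967 and 0 genes, 15 and 14 lists (48 h against 4 h), 6031 and 0 genes, 11 and 12 lists (INC424 persistent against 48 h) and 5249 and 0 genes, 13 and 13 lists (DMSO). For pairs of lines they were 6333 and 93 genes, 15 and 13 lists (BMS911543 against CYT387), 3329 and 0 genes, 9 and 9 lists (BMS911543 against INC424), 5142 and 0 genes, 16 and 13 lists (BMS911543 against SAR302503), 4911 and 131 genes, 14 and 17 lists (CYT387 against INC424), 5305 and 2183 genes, 10 and 13 lists (CYT387 against SAR302503) and 2566 and 595 genes, 12 and 10 lists (INC424 against SAR302503). The real split alone gave the real gene count or more in each of these, 1 of 10, while for lists the splits with as many, the real one included, numbered 6 (CYT387), 3 (SAR302503), 5 (INC424 4 h), 2 (INC424 48 h), 2 (INC424 persistent against 48 h), 3 (DMSO), 2 (BMS911543 against INC424), 5 (CYT387 against INC424) and 4 (CYT387 against SAR302503), and 1 in the other comparisons. For the mean of the lines 100 of 455 splits were drawn. Its gene count was 4396 (2 of 100 splits as large, the real one included, highest other 4953), the genes alike in the 4 lines 726 (1 of 100, highest other 160) and its number of lists 13 (24 of 100, highest other 19). These splits exchange libraries among lines that differ from each other, so with the line as the unit chance cannot be excluded for any of the 3. The split with 4953 genes sets CYT387 persistent libraries 2 and 3 and SAR302503 persistent library 3 apart, which points to a structure of the samples other than their groups.

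CYT387 persistent library 2 held squamous, stromal, vessel and macrophage RNA, with 140037 counts of TGFBI and 33403 of C3. TMM and upper-quartile scaling moved the stromal set only from a median log2 of 10.96 above libraries 1 and 3 to 10.69 or more. That choice accounts for little of it. A change of the line is argued against, since in libraries 1 and 3 that set was at a median log2 of 0.44 to naive. RNA from cells of another kind remains a candidate source: 10 of 10 SET2 markers, JAK2 among them, were below libraries 1 and 3, with a median log2 of -1.42. At which step it may have entered was not tested.

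DMSO and naive cells differed by 5249 genes, although both are naive cells without inhibitor. Libraries run again are argued against as the whole source, since 4765 genes changed with the run-again label as a term. RNA from other cells is left open as part of the source: 6 of the 15 marker genes tested were called without the 4 libraries richest in epithelial RNA, between the shares set for and against it (0 passed in the shared limma fit, 0 at unadjusted p < 0.05, 0 with edgeR and 0 with DESeq2). Vehicle exposure and the state of the culture at harvest cannot be told apart, since 0 libraries hold vehicle at another duration.

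MHC class II genes were higher in the CYT387 line, with HLA-DRA at 11037 against 2319 in naive cells. RNA from other cells is argued against as the whole source, since without library 2 the median log2 was 1.66 and 9 of 10 genes were called (list adjusted p = 9.2e-12). Upper-quartile scaling moved the median gene of this comparison by -0.067 log2 and left the list median at 2.07, so that choice of scaling accounts for little of the rise. No CYT387 persistent or naive library was labelled as run again. By the labels that source does not apply, and the term for it was no test of it (list adjusted p = 1.3e-11). The list's adjusted p ranged from 1.1e-12 to 0.013 over its alternatives. In libraries 1 and 3 each, 10 of 10 genes lay above every naive library, so a lasting change of this line may account for the rise; this is a hypothesis found and tested on the same data. Concentrations and the number of separate cultures are not in the labels, so whether the inhibitor or one culture's history underlies it was not tested.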

How the results depend on the processing

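Alternatives without CYT387 library 2, the 4 libraries or the signature genes were chosen after seeing the data. Pseudocounts, filters, TMM and upper-quartile scaling, the empirical Bayes options, the replicate block, the run-again term, edgeR, DESeq2 and the removal of signature genes kept every total count of genes, and where run of lists, within 1.5 times. Counts of genes moved further with sample quality weights to 9725 (BMS911543), 8878 (INC424 persistent), 7607 (the mean of the lines), 6942 (INC424 4 h), 12203 (INC424 48 h), 8345 (48 h against 4 h), 10604 (INC424 persistent against 48 h), 10987 (DMSO), 8106 (BMS911543 against INC424), 3485 (CYT387 against SAR302503), 1109 (the alike genes). In fits of the compared groups alone they were 522 (CYT387), 2395 (SAR302503), 2771 (the mean of the lines), 4422 (INC424 4 h), 10613 (INC424 48 h), 7305 (48 h against 4 h), 9335 (INC424 persistent against 48 h), 1970 (BMS911543 against CYT387), 5995 (BMS911543 against INC424), 1216 (CYT387 against INC424), 534 (CYT387 against SAR302503), 1607 (INC424 against SAR302503), 396 (the alike genes). Without CYT387 library 2 they were 6090 (SAR302503), 3316 (INC424 4 h), 5073 (48 h against 4 h), 5425 (BMS911543 against INC424), 4519 (INC424 against SAR302503). Without the 4 libraries they were 8015 (BMS911543), 7041 (INC424 persistent), 6875 (SAR302503), 6763 (the mean of the lines), 4259 (INC424 4 h), 5206 (48 h against 4 h), 8518 (DMSO), 5819 (BMS911543 against INC424), 8209 (BMS911543 against SAR302503), 6820 (INC424 against SAR302503), 1108 (the alike genes). With naive in place of DMSO the count was 4039 (INC424 48 h). Quality weights gave CYT387 library 2 a weight of 0.027, and its residual SD was 1.71 against 0.44 to 1.02 in the others; the cause of the moves was not tested. Leaving out 1 library moved some counts further, which ranged over 930 to 1109 genes (INC424 4 h), 1810 to 2295 genes (48 h against 4 h), 1662 to 3775 genes (INC424 against SAR302503), 7 to 16 lists (CYT387); it leaves 2 libraries in a group. With an estimated correlation the lists that passed numbered 3 (BMS911543), 3 (CYT387), 8 (INC424 persistent), 5 (SAR302503), 5 (the mean of the lines), 4 (INC424 48 h), 4 (48 h against 4 h), 5 (INC424 persistent against 48 h), 5 (DMSO), 8 (BMS911543 against CYT387), 3 (BMS911543 against INC424), 6 (BMS911543 against SAR302503), 8 (CYT387 against INC424), 4 (CYT387 against SAR302503), 2 (INC424 against SAR302503). With fry, which does not set a list against other genes, they numbered 21 (the mean of the lines), 22 (INC424 persistent against 48 h), 21 (DMSO), 15 (BMS911543 against INC424), 22 (CYT387 against INC424). The correlation of 48 h and persistent changes was -0.065 to 0.050, -0.085 to 0.018 with 1 library left out, and 0.39 with naive as both controls. Of 206 named changes, 196 kept direction and call in every alternative; of 4937 values, 22 lost the call and 0 reversed. Equal numbers did not pair replicates (12 of 84 pairs of residuals had r above 0.1 and 21 below -0.1). DESeq2 gave no adjusted p for 439 to 4308 genes of low count.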

Other observations

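Platelet, progenitor and survival genes changed in single lines, and their lists are given here for the mean of the lines. Of the megakaryocyte and platelet list 10 of 22 rose and 4 fell (10 and 5 adjusted over the list alone, adjusted p = 0.12), and it was called higher without CYT387 library 2 (adjusted p = 0.016). THBS1, which encodes the platelet matrix protein thrombospondin, was 24499 ± 586 in the BMS911543 line and 17380.4 ± 5452 in the CYT387 line against 665 ± 71.0 in naive cells (log2 5.21 and 4.66, the latter 4.95 without library 2), while F13A1, a clotting factor gene, fell in the BMS911543 line (log2 -4.33). Of the stem and progenitor list 2 of 10 rose and 3 fell (3 and 4 adjusted over the list alone, adjusted p = 0.25) in the mean of the lines, with GATA2, a progenitor transcription factor, at 16666 ± 8984 against 33029 ± 4653 (log2 -1.15). Of the BCL2 family 3 of 16 rose and 3 fell (3 and 3 adjusted over the list alone, adjusted p = 0.61). MCL1 fell in the BMS911543 and INC424 lines (log2 -0.92 and -0.97). Of the negative regulators of JAK-STAT signalling 1 of 15 rose and 4 fell (1 and 5 adjusted over the list alone, adjusted p = 0.25), with the phosphatase genes PTPN1 (log2 -0.72) and PTPRC (log2 -0.82) lower. Of the ABC drug transporters 1 of 7 rose and 1 fell (1 and 1 adjusted over the list alone, adjusted p = 0.43). ABCB1, the multidrug efflux pump, rose in the SAR302503 line (log2 1.21), and ABCC3 in the CYT387 line (log2 2.23, 1.76 without library 2, adjusted p = 0.072 in a fit of the 6 libraries alone).

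Interferon genes moved in opposite directions within their list. Of the interferon response 5 of 32 rose and 5 fell (6 and 6 adjusted over the list alone, adjusted p = 0.61) in the mean of the lines. IFIT2 was 569 ± 277 against 172 ± 38.4 (log2 1.56), and BST2, a membrane antiviral factor, 1404 ± 886 against 3214 ± 536 (log2 -1.43). Of the p53 targets 6 of 18 rose and 4 fell (6 and 4 adjusted over the list alone, adjusted p = 0.92). The death receptor gene TNFRSF10B was 522, 1223, 515 and 869 in the BMS911543, CYT387, INC424 and SAR302503 lines against 1949 ± 299 (log2 -1.42). Of the lymphoid list 3 of 13 fell (3 adjusted over the list alone, adjusted p = 0.76), with CD4 (log2 -1.25), which monocytic cells also express, and CD79A (log2 -1.38) lower. The mitochondrially encoded list did not pass in the mean of the lines (adjusted p = 0.52). After 48 h of INC424 replication-dependent histones rose in part (4 of 11 rose, 4 adjusted over the list alone, adjusted p = 0.062 for the list, and 0.042 to 0.049 with TMM scaling or without DMSO library 3 or INC424 48 h library 1 or 2), with HIST1H2AC at log2 2.14.

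Of the genes named here, some also moved the same way in DMSO-treated cells against naive, without inhibitor: THBS1 (at 7502 ± 422), MCL1 (log2 -0.85), PTPN1 (-0.66), PTPRC (-0.91), TNFRSF10B (-2.04) and CD4 (-1.27).

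The test of JAK-STAT targets was chosen after the result was seen, and that of the controls before. One hypothesis was that the shift from 4 h to 48 h of INC424 is the shift between naive and DMSO cells, or its opposite. Across genes the correlation of these changes, which share no library, was r = -0.26, between the values set in advance for and against it, so the data leave it open. Another was that the persistent INC424 line keeps low the JAK-STAT targets that fell at 4 h: 6 of 11 were below naive and 1 was above (4 of 11 were below naive with DMSO), which also lies between the values set for and against it.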
